A study of Sorghum bicolor with 14 samples.

How the data were processed

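RNA was measured by sequencing in the middle internode of the stem of sorghum (Sorghum bicolor), in the grain variety M35-1. The 14 libraries form 7 groups of 2. Per the labels, 4 groups are development stages of field-grown plants: floral initiation, booting (when the panicle swells inside the flag leaf sheath), milky stage and soft dough (the grain filling stages that follow flowering). The other 3 groups are pot-grown plants from which water was withheld from the flag leaf stage. They were harvested at booting when the soil moisture meter read about 13% (D1), 7% (D2) or 2% (D3). Total RNA was taken with a modified trizol method and libraries were made with a stranded total RNA kit, per the labels' protocols.

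The values used are FPKM (fragments per kilobase of transcript and per 1000000 mapped fragments) that the authors deposited, per the file headers. The submitters' processing notes name cutadapt 1.8.1, Bowtie2 2.2.9, HISAT2 2.0.5 and Cuffdiff, without saying which step each served; the genome build and the filters are not given in the sources used here. The values come as a development table of 34755 loci and a drought table of 32726 loci. Each has its own locus models and 1 FPKM column per group. Both libraries of a group name the same column in their labels, so the column was taken as the authors' pooled value of the group. No value per library was used here. No difference therefore has a replicate check, and no SD, standard error or p-value is given. The strand setting of the counting is not given in the sources used here, so loci that overlap on opposite strands may share fragments.

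Loci carry sorghum annotation IDs, several IDs or none. In the development table, 31539 loci have 1 ID, 1213 have several and 2003 have none. In the drought table, 31496 have 1 and 1230 have several. The files do not pair these IDs with gene names, and 0 of the 34129 different IDs matched the reference table of gene symbols used here. The 31 gene lists fixed beforehand for cell walls, sugars, drought response and other processes therefore had 0 members found and were not run. By the fixed rule for that case, at most 2 IDs that rose and 2 that fell are named per comparison. These are the largest changes among loci with 1 ID and at least 5 FPKM in the higher column. Positions are those printed in the file.

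A locus counted as measured in a comparison with at least 1 FPKM in the higher of the 2 columns. It was called higher or lower when log2(FPKM + 1) differed by at least 1. A difference on this scale understates the change of low loci. Several loci can share one printed range, as 5485 do in the development table and 4762 in the drought table, so fragments may have been divided among overlapping models. A locus listed at exactly 0 can be a failed estimate, so it is described only as listed at 0, with no fold against it. The 2 tables were normalized separately. Values across them were compared only for the 26825 loci with the same IDs and the same range in both.

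Library totals were not among the values used, so the depth is unknown. The low values show a grain: the smallest non-zero values, taken as the 1st percentile of FPKM times kilobases among loci of at most 3000 bp, correspond to 60.2 to 89.6 such steps for a locus of 1 kb at 1 FPKM. The largest step, at D1 (60.2 steps), was 1.49 times the smallest, at D2 (89.6 steps), across the 7 columns. This difference therefore falls on D2 against D1. If 1 step is 1 fragment in 1 library, a locus of 1 kb at 1 FPKM rests on about that many fragments. The method of calling was tested on simulated data with Poisson noise at this grain. For soft dough against floral initiation, over 34755 loci of which 200 were changed, 100 of 100 loci changed 3-fold and 100 of 100 changed 8-fold were called the right way, with 0 calls among unchanged loci. For D3 against D1, over 32726 loci, the same numbers were 100 of 100, 100 of 100 and 0. The changed loci were drawn only from those at 5 FPKM or more in the earlier column. At that level a 3-fold change passes the call threshold by its size, so the recovery was nearly fixed beforehand. The simulation does not show how often changes at lower loci are called. It holds counting noise alone and no difference between plants. Fragments were simulated from the length of the printed range, which can exceed the transcript length that FPKM uses. The simulated noise may therefore be too small, and the 0 calls among unchanged loci do not measure the counting noise of these columns.

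Neighbouring loci were ordered along each chromosome, with 1 locus per printed range, and runs of 4 or more measured loci called in one direction were counted. The calls were shuffled within chromosomes 1000 times to give the number of runs without an order. This step, the counts by stage of the highest column and the description by region were chosen after seeing the data. The run finder recovered 10 of 10 planted runs among 17390 shuffled loci. The planted runs were written into the calls themselves, so this checks the search alone and not runs from noisy values. Levels of a region are medians over its loci at 1 FPKM or more in at least 1 column of the table.

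Before the data were examined, the following alternatives were fixed: a pseudocount of 0.1 or 5, no filter or a filter at 5 FPKM, columns rescaled to sum to 1000000, median-of-ratios size factors, and the 50 loci with the highest mean left out. Counting 1 row per printed range, and leaving out loci listed at 0 beside 20 FPKM or more, were added after seeing the data. Fits with a column per library, a replicate block or a library left out could not be run on pooled columns. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.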

Results

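Transcript levels in the middle stem internode of sorghum were measured at 4 development stages and at 3 levels of soil moisture, with 2 libraries per group and 1 pooled FPKM value per locus and group. The sums of FPKM over all loci ran from 647966 at floral initiation to 720661 at booting. Between 16051 loci (D2) and 17265 loci (soft dough) were at 1 FPKM or more. The 10 highest loci took 5.31% (D2) to 8.93% (milky stage) of the sum. Across 13949 loci, which are not independent replicates, log2(FPKM + 1) correlated most closely between D1 and D2 (Pearson r = 0.97, Spearman rho = 0.97). Floral initiation and booting (r = 0.95, rho = 0.95) and milky stage and soft dough (r = 0.95, rho = 0.94) were also close, and booting and milky stage less so (r = 0.89, rho = 0.89). The lowest correlation was between soft dough and D2 (r = 0.82, rho = 0.81), which come from separately normalized tables. With pooled columns, none of the differences below has a replicate check.

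**Figure D1:**
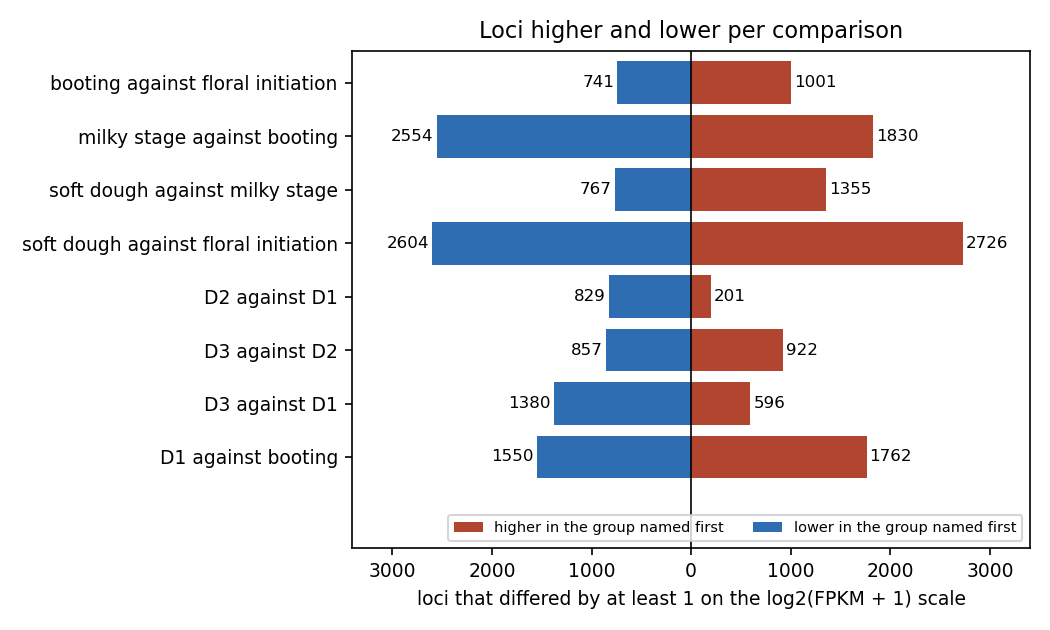
Number of loci (horizontal axis) whose log2(FPKM + 1) was higher (right) or lower (left) by at least 1 in the group named first, for the 8 comparisons on the vertical axis. The step from booting to milky stage had the most loci of the 3 development steps, with 1830 higher and 2554 lower, and D2 against D1 had 201 higher and 829 lower.

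The comparison of soft dough with floral initiation spans the whole series of stages and asks how the internode differs between its early and its late state. Of 18568 measured loci, 2726 were higher and 2604 lower at soft dough. Sobic.010G177800, on chromosome 10 at 51567423 to 51568369, had 7.44 FPKM at floral initiation, 91.4 at booting, 244 at milky stage and 1490 at soft dough, a log2 difference of 7.46 over the span. Sobic.003G088400 (chromosome 3, 7689355 to 7690085) stayed between 0.603 and 2.23 FPKM in the first 3 stages and reached 265 at soft dough. Among the falls, Sobic.005G046700 (chromosome 5, 4444213 to 4445054) went from 969 FPKM to 529, 54.2 and 3.62 along the stages, a log2 difference of -7.71. Sobic.002G109100 (chromosome 2, 13271050 to 13272067) went from 102 FPKM to 33.2, 1.35 and 0.105, a log2 difference of -6.54. A rise of at least 3 log2 units was seen at 232 loci and a fall of that size at 204. The near balance of directions turned to 2607 higher and 2721 lower with the 50 most abundant loci left out.

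Booting against floral initiation, the first step, had 1001 loci higher and 741 lower of 17889 measured. Sobic.005G140001 (chromosome 5, 59525286 to 59527098) stood at 285 FPKM at booting and at 0.370, 0.102 and 0.180 FPKM at floral initiation, milky stage and soft dough. Sobic.004G337132 (chromosome 4, 66881273 to 66881432) was listed at 0 at floral initiation and soft dough, and had 149 FPKM at booting and 44.1 at milky stage. Its printed range is the shortest among the named loci. Since FPKM is per kilobase, few fragments can give a high value there. Sobic.001G519700 (chromosome 1, 78556200 to 78558727) fell from 35.03 to 0.0602 FPKM at booting and was at 11.6 at milky stage. Sobic.010G031500 (chromosome 10, 2553243 to 2554559) was listed at 0 at booting, between 21.3 FPKM at floral initiation and 27.7 at milky stage. On chromosome 10, from 51567423 to 51651891, 5 neighbouring loci were all higher at booting, with a median of 12.4 FPKM at floral initiation and 89.5 at booting. The direction of the whole depended on the scaling: 57.5% of the calls were higher as deposited, but 44.8% (965 higher, 1191 lower) with columns rescaled to the same sum and 45.5% (827 higher, 991 lower) with the 50 most abundant loci left out. These scalings moved the median log2 change of the measured loci from 0.03 to -0.11 and -0.11, and median-of-ratios size factors gave 976 higher and 773 lower.

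Milky stage against booting was the step with the most calls in development, with 1830 loci higher and 2554 lower of 18209 measured, or 24.1% of them. Sobic.009G038000 (chromosome 9, 3571339 to 3571908) rose from 0.987 to 216 FPKM and had 93.2 at soft dough. Sobic.007G003600 (chromosome 7, 342898 to 345271) had 106 FPKM at milky stage, 0.0389 at booting and 2.30 at soft dough. Sobic.005G140001 fell by 8.02 on the log2 scale, and Sobic.003G217632 (chromosome 3, 55308083 to 55311807) went from 84.3 to 0.00899 FPKM. On chromosome 2, 8 neighbouring loci between 66529281 and 66566613 were lower at milky stage, with a median of 6.27 FPKM at booting, 0.129 at milky stage and 0.0632 at soft dough. On chromosome 9, 5 neighbouring loci between 3571339 and 3606537, the first of them Sobic.009G038000, were higher, with medians of 0.885, 0.987, 14.2 and 11.97 FPKM along the stages. The median absolute log2 change over measured loci was 0.52, against 0.32 for the step before and 0.34 for the step after.

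Soft dough against milky stage, the last step, had 1355 loci higher and 767 lower of 17947 measured. Sobic.006G025900 (chromosome 6, 4669311 to 4670061) rose from 1.58 to 1008 FPKM and Sobic.006G025400 (chromosome 6, 4498652 to 4499488) from 0.636 to 341. Both lie in a run of 6 neighbouring loci from 4498652 to 4684050 on chromosome 6 that all rose, by 4.91 to 8.61 on the log2 scale. The medians of the run were 5.50 FPKM at floral initiation, 0.0770 at booting, 0.870 at milky stage and 312 at soft dough. Sobic.004G337132 was listed at 0 at soft dough, and Sobic.004G303466 (chromosome 4, 64241689 to 64242477) fell from 42.1 to 0.227 FPKM. On chromosome 3, 10 neighbouring loci between 28831985 and 28861779 fell, with medians of 0.140, 4.67, 5.21 and 0.143 FPKM along the stages. A run of 6 loci between 38333551 and 38374369 on the same chromosome fell at this step as well, with medians of 0.162, 3.64, 5.34 and 0.145 FPKM. In the drought table, which lists no loci without an ID, only 1 locus at 1 FPKM or more lay within each of these ranges on chromosome 3. Whether the neighbours in these runs are separate transcripts was not tested.

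**Figure D2:**
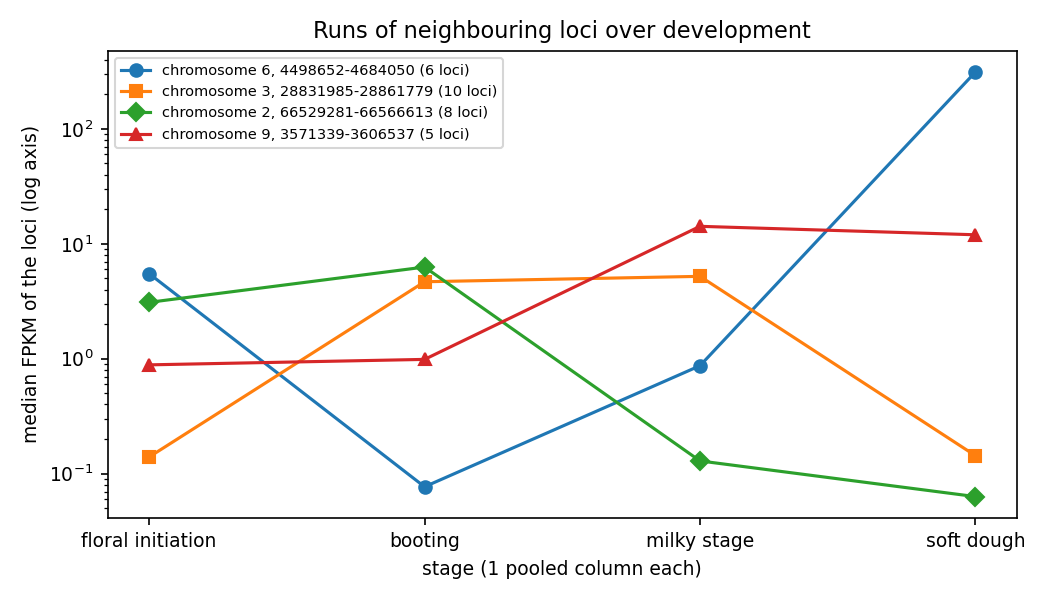
Median FPKM (vertical log axis) of the loci of 4 runs of neighbouring loci at the 4 development stages (horizontal axis), 1 pooled column per stage. The run on chromosome 6 reached 312 FPKM at soft dough, and that on chromosome 3 was above 4 FPKM only at booting and milky stage.

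**Figure D3:**
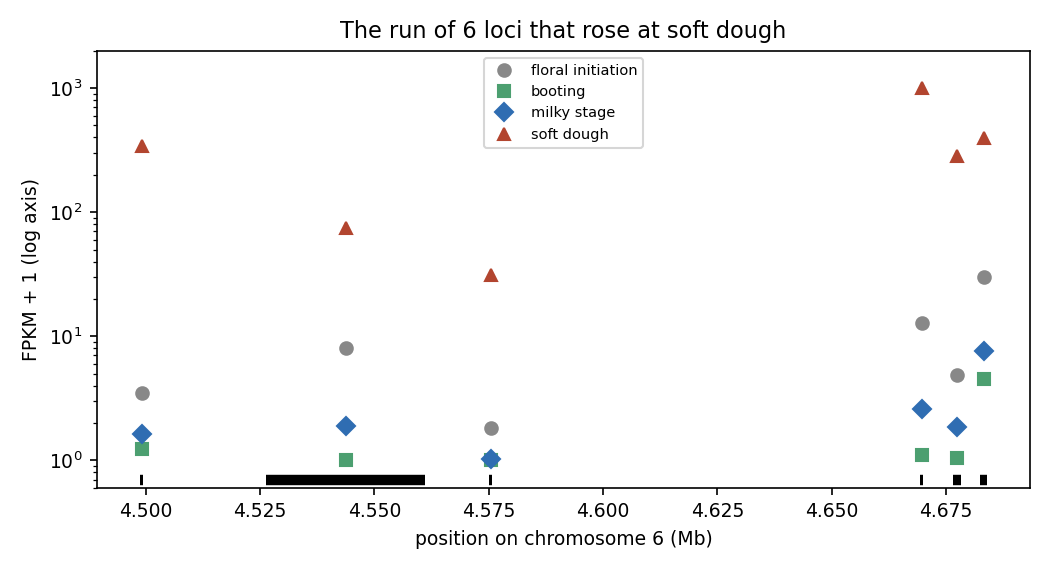
FPKM + 1 (vertical log axis) of the 6 loci of the run on chromosome 6, by position in Mb (horizontal axis). Each point is a locus at a stage, and the black bars mark the printed ranges of the loci. At soft dough the loci had 29.9 to 1008 FPKM, and at the other stages none was above 29.0 FPKM.

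The stages fell into an early and a late pair. With the early stages (floral initiation and booting) both at least 1 log2 unit above the late ones (milky stage and soft dough) there were 1165 loci, and 873 had both late stages above both early ones. The other pairings of the stages separated 97 loci (floral initiation with milky stage) and 232 loci (floral initiation with soft dough). A steady course over all 4 stages, with a span of at least 1 log2 unit, was seen at 774 rising and 945 falling loci, 1719 together. The 12 possible orders of the columns, counted without direction, included 3 with at least as many, the real one among them, the highest other order having 1809, so the count does not single out the order of the stages. Of 9082 loci that varied by at least 1 log2 unit over development, 26.1% were highest at floral initiation, 25.3% at booting, 20.5% at milky stage and 28.1% at soft dough. These shares depended on the scaling: with the 50 most abundant loci left out, 2930 loci were highest at floral initiation, 1737 at booting, 1670 at milky stage and 2802 at soft dough, and with columns rescaled to the same sum 3252, 1918, 1744 and 3342, where the deposited values gave 2372, 2298, 1858 and 2554.

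D2 against D1, soil moisture of about 7% against 13%, asks what changed between these readings. The columns were close, with a median absolute log2 change of 0.25, and 201 loci were higher and 829 lower of 16865 measured. Sobic.010G031800 (chromosome 10, 2563884 to 2566760) had 0.535 FPKM at D1, 24.8 at D2 and 22.7 at D3. Sobic.005G169200 (chromosome 5, 64809823 to 64811829) had 0.846, 29.3 and 4.84 FPKM. Sobic.009G043900 (chromosome 9, 4198823 to 4200683) had 64.8 FPKM at D1, 0.0504 at D2 and 0.174 at D3. Sobic.004G089801 (chromosome 4, 7597117 to 7627268) was listed at 0 at D2, between 55.4 FPKM at D1 and 58.8 at D3. On chromosome 9, a run of 5 loci from 3551576 to 3606537 fell, with medians of 15.98 FPKM at D1, 4.94 at D2 and 7.71 at D3. It holds Sobic.009G038000, which had 71.1, 17.6 and 10.5 FPKM. Lower loci made up 80.5% of the calls, and 13 loci were higher and 60 lower among those at 100 FPKM or more.

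D3 against D2, soil moisture of about 2% against 7%, had 922 loci higher and 857 lower of 16739 measured. Sobic.001G304201 (chromosome 1, 58813599 to 58814288) had 24.7 FPKM at D1, 6.77 at D2 and 281 at D3, and Sobic.004G089801 returned from a listed 0. Sobic.009G119200 (chromosome 9, 46821033 to 46826334) fell from 550 to 6.93 FPKM and Sobic.002G122200 (chromosome 2, 16204009 to 16213249) from 30.3 to 0.0121. On chromosome 6, 7 neighbouring loci between 57419856 and 57445069 fell together, with medians of 110 FPKM at D1, 147 at D2 and 24.6 at D3. The highest of them went from 882 FPKM at D2 to 158 at D3. The balance of directions turned with the scaling, to 981 higher and 1056 lower with columns rescaled to the same sum and to 858 and 922 with the 50 most abundant loci left out.

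D3 against D1 spans the drying from about 13% to 2% soil moisture, with no watered pot group analysed here, and had 596 loci higher and 1380 lower of 17045 measured, so that 69.8% of the calls were lower. Sobic.003G244600 (chromosome 3, 58393939 to 58395378) rose from 12.5 FPKM to 128 and 557 along the levels, and Sobic.006G061900 (chromosome 6, 41719162 to 41721830) from 1.27 to 28.5 and 108. Sobic.009G119200 fell from 870 to 6.93 FPKM, a log2 difference of -6.78, and Sobic.009G043900 fell by 5.81 on that scale. A run of 6 loci on chromosome 6, from 54712016 to 54759119, was lower at D3, with medians of 101, 123 and 28.1 FPKM. Of the 829 loci lower at D2, 437 were also called lower at D3 against D1, and 228 were called higher at D3 than at D2. The 829 were picked by a low D2 value that D3 against D2 uses again, so chance low values there would give part of the 228. Steady courses were seen at 264 rising and 1018 falling loci, 1282 together. The highest other of the 3 possible orders gave 1179. Of 2960 loci that varied by at least 1 log2 unit, 47.4% were highest at D1, 18.9% at D2 and 33.7% at D3.

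**Figure D4:**
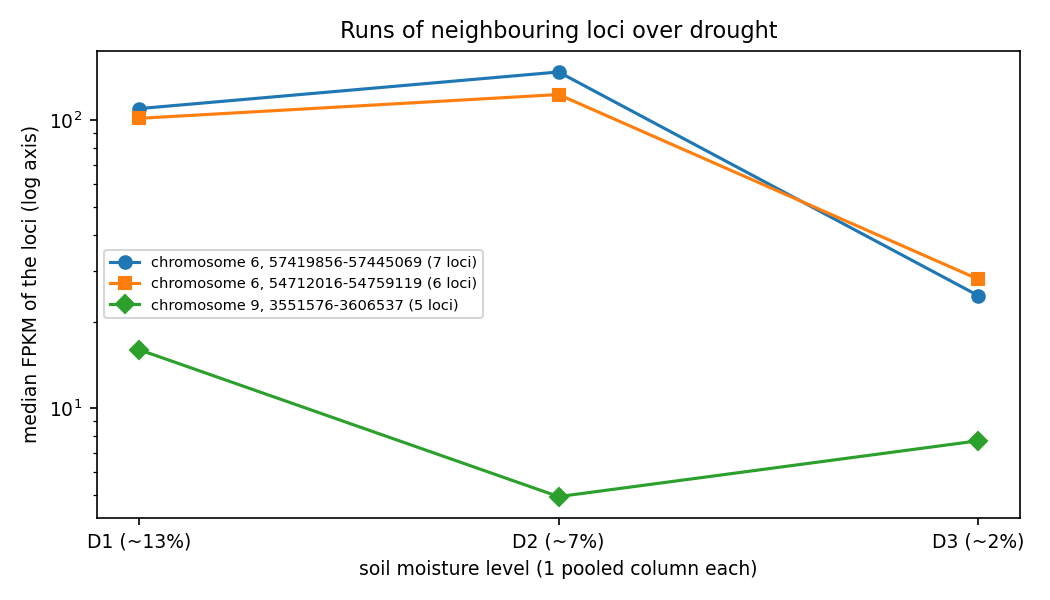
Median FPKM (vertical log axis) of the loci of 3 runs of neighbouring loci at the 3 soil moisture levels (horizontal axis), 1 pooled column per level. Both runs on chromosome 6 were higher at D2 than at D1 and fell at D3, to 24.6 and 28.1 FPKM, and the run on chromosome 9 was lowest at D2, at 4.94 FPKM.

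D1 against booting compares plants at one stage, in drying pots and in the field. Of 12961 measured loci with the same IDs and range in both tables, 1762 were higher and 1550 lower at D1. The models within a range may still differ between the tables. Sobic.009G119200 had 870 FPKM at D1 and 0.162 at booting, and Sobic.002G384400 (chromosome 2, 73966176 to 73967637) had 400 and 0.376. Sobic.010G178000 (chromosome 10, 51603656 to 51604401) had 0.849 FPKM at D1 and 439 at booting, and Sobic.003G231800 (chromosome 3, 57122090 to 57122904) had 1.43 and 234. D2 differed from booting at 1715 higher and 1986 lower loci, and D3 at 1361 and 1684. The tables were normalized separately. Growth in pots, withheld water, the table and the last digit of the library titles cannot be told apart here. Median-of-ratios size factors turned the balance for D1 to 1595 higher and 1732 lower, and columns rescaled to the same sum turned that for D2 to 2276 higher and 2171 lower. Those size factors moved the median log2 change from 0.09 to -0.02 for D2 and from 0.10 to -0.01 for D3.

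Development and drought changes were set side by side for 11856 loci measured both in soft dough against floral initiation and in D3 against D1, which share no column. Higher at soft dough and lower at D3 were 315 loci, where independent lists would share 122. Lower in both were 190 loci (119 expected), higher in both 76 (54.1 expected), and lower at soft dough but higher at D3 107 (52.4 expected). Across loci, which are not independent replicates, the log2 changes had a Pearson r of -0.01 and a Spearman rho of -0.01. The overlap was relatively larger for the step to booting: 188 of the 581 loci higher at booting than at floral initiation were lower at D3 than at D1, where 41.6 were expected, a ratio of 4.52. For the same step, 56 loci were higher in both (19.4 expected), 26 were lower at booting and higher at D3 (12.2 expected) and 45 were lower in both (26.2 expected), so all 4 combinations lay above expectation. On chromosome 6, a run of 5 loci from 57419856 to 57442937 was higher at booting than at floral initiation, and a run of 5 loci whose range overlaps it, from 57422956 to 57445069, was lower at D3 than at D1.

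The titles of the libraries end in 1 for floral initiation and the drought groups and in 2 for booting, milky stage and soft dough, and the labels do not say what the digit marks. All 3 columns of the latter kind lay at least 1 log2 unit above all 4 others at 26 loci and below them at 2 loci, 28 together. At these loci, the digit and the group cannot be told apart. The same holds for every call in a comparison whose 2 groups differ in the digit. These are booting against floral initiation, soft dough against floral initiation, and each drought group against booting.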

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

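The pseudocount moved the counts most. With a pseudocount of 5, all 38 counts compared fell outside 1.5 times their value. Loci higher and lower became 433 and 252 for booting against floral initiation, 850 and 1306 for milky stage against booting, 596 and 329 for soft dough against milky stage, and 1373 and 1349 for soft dough against floral initiation. In the drought groups they became 64 and 320 for D2 against D1, 406 and 398 for D3 against D2, and 255 and 684 for D3 against D1. D1 against booting gave 903 and 815. Loci rising and falling at every step became 433 and 525 in development, and 104 and 518 in drought. Overlaps of loci lower at D3 against D1 became 123 and 79 with loci higher and lower at soft dough, and 79 and 11 with loci higher and lower at booting. The split by title digit became 13 loci. A larger pseudocount shrinks every log2 difference by construction. With a pseudocount of 0.1, 9 of the 38 counts moved that far: 1209 loci lower at booting against floral initiation, 1158 lower at soft dough against milky stage, 334 higher and 1348 lower at D2 against D1, 907 higher at D3 against D1, 419 rising at every step of drought, 97 lower at both booting and D3, 84 in the split by title digit, and 1389 with both late stages above both early ones. A filter at 5 FPKM gave 130 loci higher at D2 against D1 and 207 higher at soft dough and lower at D3, since fewer loci enter. Rescaling to one sum gave 1191 loci lower at booting against floral initiation and 91 lower at both booting and D3. Rescaling to 1000000 also raises all values against the pseudocount, and which of the 2 effects moved these counts was not tested. The other 36 counts under each of these 2 settings, and all 38 under no filter, median-of-ratios factors, the 50 loci left out and the alternatives added after seeing the data, stayed within 1.5 times. No filter changes nothing at a pseudocount of 1, since a difference of 1 log2 unit needs 1 FPKM.

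No log2 change of a named locus changed sign where it could be computed. This is no check of them, since they were picked as the largest changes. No pseudocount or filter can turn a sign, and the rescalings were small beside these changes. Leaving out loci listed at 0 kept 26 of the 32. With pseudocounts of 0.1 and 5, 26 and 28 of 32 shifted by 0.58 or more, and with columns rescaled to one sum 3 did, each to a larger size (-5.67, -5.08 and 10.25). No paired analysis was possible because the columns are pooled over the libraries of a group and carry no replicate number. For the same reason the fits that leave out a library, add a replicate block or keep only the groups compared were not run, nor were the 31 gene lists, which had 0 members found. The depth and the spread between plants are unknown, so what they limit was not measured.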

Other observations

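The tests of scaling, of low loci and of the D1 column, that of direction and the count of splits were chosen after the result was seen, as were the runs of neighbours themselves.

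Loci that the development table lists without an annotation ID were called more often than loci with 1 ID at the first and the last step, but not at the middle step, and about as often over the whole span. Of 2003 such loci, 58.3% reached 1 FPKM in at least 1 stage. They were called in 20.8% of measured cases at booting against floral initiation, where loci with 1 ID were called in 9.11%, and in 20.7% against 11.3% at soft dough against milky stage. At milky stage against booting the rates were 21.4% and 24.4%, and at soft dough against floral initiation 29.3% and 28.9%. The loci without an ID were at a lower level, with a median log2 FPKM of 2.07 against 3.67 in the higher column of the first step. Chromosomes 5 and 8 lay outside the range of the other 8 at D3 against D1, where 5.35% and 5.03% of their measured loci were higher (2.54% to 3.63% on the others) and 5.61% and 5.03% lower (7.48% to 8.96%). They also did at booting against floral initiation, with 6.86% and 6.45% lower (2.99% to 5.67%) and 4.35% and 4.02% higher (5.17% to 6.37%). At D2 against D1 both lay outside the others for higher loci only, with 3.07% and 1.85% (0.793% to 1.36%). At milky stage against booting both did so for lower loci only, with 12.8% and 11.6% (12.99% to 14.99%). At D3 against D2 chromosomes 5 and 8 did not stand apart together, with 6.24% and 4.67% higher, and chromosomes 9 and 6 at 6.16% and 4.81%. Nor did they at soft dough against milky stage or against floral initiation. A locus model of 106 kb on chromosome 10, from 52122843 to 52228422, with 4 IDs, had 2089 FPKM at floral initiation and was listed at 0 at the other stages. Its model of the same range in the drought table had 2226 FPKM at D1, 2015 at D2 and was listed at 0 at D3. In the development table, 24 loci had 20 FPKM or more in a column and a listed 0 in another, and in the drought table, 2 had.

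Loci lower at D2 than at D1 outnumbered higher ones, 829 to 201. The values argue against the scaling of the columns, since the lowest share of lower calls over the 3 other scalings was 76.1%, and against few fragments behind low loci, since 82.2% of the calls were lower at 100 FPKM or more. A D1 column that stands apart from the others stays open. Of the loci lower at D2, 52.7% were also called lower at D3 against D1, a share that depends on the call threshold. Without the threshold, 80.5% were below D1 at D3, with a median log2 change of -1.06, where D2 had -1.32. Both comparisons share the D1 column, so chance values in it alone would give part of these shares. Of the 201 loci higher at D2, 29.4% were still called higher at D3. A fall that lasts through the drying may give such shares too, and no second D1 value was analysed here to decide. Whether the D2 column stands apart was not tested. Its Pearson r with each development column was the lowest of the 3 drought columns (with booting 0.853, where D1 had 0.879 and D3 0.878). D1 and D2 were still the closest pair (r = 0.97).

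Runs of 4 or more neighbouring loci called in one direction numbered 35 at soft dough against floral initiation (mean of shuffles 13.0, highest 26), 11 at booting against floral initiation (mean 1.19, highest 4), and 7 at D3 against D1, all 7 lower (mean 0.701, highest 4). At milky stage against booting there were 14, and 18 of 1000 shuffles gave as many; with columns rescaled to sum to 1000000 there were 23, the one run count of 7 that moved by over 1.5 times under a scaling. Overlapping models that share reads are a candidate explanation, but among 15097 loci that overlap no other there were 27 runs at soft dough against floral initiation, where the highest of the shuffles had 25. Reads split between near-identical neighbours could not be settled: within 24 runs of 5 or more, the SD of the log2 changes was 0.814 (median) of that among all loci called in the direction, ranging from 0.339 to 3.71. Several of these runs are the same region met again in comparisons that share a column, so they are not separate cases. No biological explanation was tested.

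Loci higher at booting than at floral initiation were often lower at D3 than at D1 (188 loci), and all 4 combinations of direction lay above expectation, with higher in both next at 2.89 times. Low loci were called more often (12.8% in the lowest 5 of 20 bins of mean level against 4.59% in the highest 5 at booting, 14.2% against 8.83% at D3), but the overlap was 4.12 times the 45.6 expected within the bins, which argues against level as the whole cause. Loci that vary between any 2 columns, with no link of direction, may give part of the overlap: among 286 loci called in both, 1 per window of 100 kb, the odds ratio of the same direction was 0.50 and 39 of 1000 shuffles of direction lay as far from 1, but over the other scalings it was up to 0.67 and up to 96 shuffles did, so such loci stay open as the cause. Over all loci called in both, the odds ratio was 0.52 for this step, 0.45 for milky stage against booting and 0.43 for soft dough against floral initiation, but it turned to 1.75 for soft dough against milky stage, where lower in both was 3.67 times expectation. No biological explanation was tested.

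The split of the columns by title digit separated 28 loci. Of the 35 splits of the 7 columns into 3 and 4, 7 separated as many, so chance cannot be excluded for it. The highest other split, the 3 drought columns against the 4 development columns, separated 443 loci, several times as many. This points to a structure of the columns: the drought groups differ from the others in the table, the growth in pots and the withheld water, which cannot be told apart.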
